A study of Homo sapiens with 36 samples.

How the data were processed

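Gene expression was measured by sequencing of polyA mRNA in FLO1 and OE33, 2 human esophageal adenocarcinoma cell lines. Cells carried a control shRNA (shControl) or 1 of 2 shRNAs against APE1, the protein encoded by APEX1 (shAPE1#1 and shAPE1#3). They were left unexposed or were given acidic bile salts (ABS; 200 µM at pH 4) for 20 min, followed by 6 h of recovery in complete medium. Each of the 12 groups had 3 libraries, which the labels describe as independent biological replicates, so 36 libraries were compared. FLO1 was grown in DMEM and OE33 in RPMI1640, so medium and line cannot be told apart. The column of FLO1 shAPE1#3 replicate 3 after ABS has an additional suffix and a serial number outside the run of the other columns; it was used as its name gives it.

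The deposited file holds raw read counts per Ensembl gene, 1 column per library. The authors' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.5.2 with genome build GRCh38. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Of 57500 gene IDs, 56410 were matched to a symbol and to coordinates in GENCODE release 29; the others held 0.082% of the counts. Without a stated strand setting, a gene and its antisense partner (JDP2 and JDP2-AS1, DNAJC9-AS1) cannot be told apart. Counts of near-identical genes are uncertain: HSPA1A and HSPA1B, with the related HSPA6; AKR1C1, AKR1C2 and AKR1C3; the SPRR family; MAGEA3; and the pseudogenes SLC6A10P, DND1P1 and SNRPGP10. Mitochondrial tRNAs are poorly captured by selection on polyA, so their counts may reflect partial transcripts.

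Library totals were 20.7 to 40.7 M counts (M, 1e6), with medians of 29.6 M in FLO1 and 27.45 M in OE33. Between 20457 and 24862 genes were detected per library. Mitochondrial genes took 2.87 to 4.07% of the counts and the 50 most abundant genes 14.0 to 17.6%. No 2 replicates were copies of each other: over 36 pairs of libraries within groups, chi-square per degree of freedom was 2.47 to 77.72 across genes.

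Differences were tested per line over all 18 libraries with edgeR 4.0.16 in R 4.3.3: TMM normalization, the default filterByExpr filter, 1 coefficient per group, and the robust quasi-likelihood test with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The filter left 16868 genes in FLO1, 15540 in OE33 and 18199 in the fit of both lines. The comparisons were ABS in shControl cells; ABS in shAPE1 cells; knockdown against shControl, unexposed and after ABS; the interaction of knockdown and ABS; shAPE1#3 against unexposed shAPE1#1; and the differences between lines (OE33 minus FLO1) of the ABS response in shControl cells and of the mean unexposed effect of both shRNAs. Within a line, knockdown, ABS in shAPE1 cells and the interaction counted only genes called with both shRNAs and with 1 sign. In OE33 both shAPE1 groups may carry the same hairpin, which could not be decided. The difference between lines in the knockdown effect was 1 contrast on the mean of both shRNAs, without that limit. Both shRNAs are set against the same shControl libraries, which makes their effects correlate by chance. Groups of 3 cannot be split to give each shRNA its own controls, so shared calls were also counted in 20 simulations in which neither shRNA had an effect. These simulations drew only the spread between libraries, for each gene on its own. They cover neither a spread that genes share nor a shift of all shControl libraries.

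Genes to be named followed a rule. APEX1 was always reported. For each comparison the rule took up to 12 higher and 12 lower genes with the largest change among called genes with a mean log2 CPM of at least 1, a symbol, and libraries that do not overlap between the groups with each shRNA (chance gives 10% for 3 against 3). For interactions and differences between lines it took up to 8 each way without the condition on overlap. Up to 4 called members of each gene list were added, or the 2 members with the highest level where none was called.

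The 27 gene lists held 559 genes, of which 1 (SOD2) had no counts. They were base excision repair; homologous recombination and Fanconi anemia; targets of p53, NRF2, NF-kB, YAP/TEAD and HIF1; immediate early and AP-1 genes; the integrated stress response; ER chaperones and the unfolded protein response; heat shock; cholesterol biosynthesis; bile acid and xenobiotic receptors and transporters; mitosis; DNA replication; interferon-stimulated genes; mesenchymal, epithelial, columnar and squamous markers; lysosome and autophagy; metallothioneins; mitochondrially encoded and nuclear oxidative phosphorylation genes; and markers of fibroblasts, immune cells and endothelium. Lists were tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over all lists and contrasts of a line. The list contrasts of knockdown used the mean of both shRNAs. Lists with fewer than 3 measured members were not tested, which left out fibroblast and endothelial markers in OE33.

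The comparisons, gene lists, naming rule and first set of alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a filter of 1 CPM in 3 libraries, a replicate block, a fit to only the groups compared, each library left out in turn, and overlaps at an adjusted p of 0.01. Alternatives added after seeing the data were a correction for GC content (offsets from 20 bins of transcript GC, from genes with a mean log2 CPM of at least 3), leaving out genes at most 0.5% of their level in the other line, list tests without FLO1 shControl ABS replicate 2, list tests of the differences between lines, leaving out libraries outside the groups compared, and the gene sets used to test for exchanged hairpins. Further corrections built from the other line's spread within groups were tried after seeing the data and not kept. Other splits of the same libraries were counted, all 10 for 3 against 3 and otherwise 100 drawn with a fixed seed.

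The pipeline was tested on simulated data with 200 changed genes. The changed genes had a mean log2 CPM above 1, and counts were drawn for each gene on its own, without a spread that genes share. With a 2-fold change it recovered 96.0 and 99.5% of genes for ABS in shControl cells (FLO1 and OE33), 95.0 and 96.0% for knockdown called with both shRNAs, and 76.0 and 86.0% for the interaction. With a 1.5-fold change, recovery was 63.5 and 86.0%, 60.0 and 75.5%, and 11.5 and 45.5%. False calls numbered at most 12 and no gene was called in the wrong direction. Of 27 lists, the changed list was called in each line and 0 unchanged lists were. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.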

Results

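PolyA mRNA was sequenced from 2 human esophageal adenocarcinoma cell lines, FLO1 and OE33. Each line carried a stable control shRNA (shControl) or 1 of 2 shRNAs against APE1 (shAPE1#1 and shAPE1#3), an endonuclease of base excision repair that also acts on transcription factors. Cells were left unexposed or received acidic bile salts (ABS) for 20 min and were collected after 6 h of recovery. The series asks what APE1 does for the transcriptional adaptation of tumor cells to simulated reflux. The 12 groups had 3 libraries each, 36 in all. Library totals ranged from 21.8 M to 40.7 M counts in FLO1 and from 20.7 M to 38.0 M in OE33 (M, 1e6 counts). Levels below are in CPM (counts per 1e6 counts), as mean ± SD with n = 3 libraries per group, and effects are log2 fold changes ± SE. Genes named for the size of their change within a line had no overlap between the libraries of the 2 groups compared, which chance gives in 10% of genes for 3 against 3.

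The first question was how far each shRNA lowered its target. APEX1 (ENSG00000100823; GRCh38 chromosome 14, 20455191 to 20457772, plus strand, protein coding) stood at 200.4 ± 3.74 CPM in FLO1 shControl, 25.5 ± 0.258 with shAPE1#1 and 37.4 ± 1.14 with shAPE1#3. In OE33 the levels were 193.9 ± 5.00, 23.9 ± 2.10 and 22.0 ± 0.559 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment APEX1 fell by -2.97 ± 0.09 (adjusted p = 8.64e-16) and -2.42 ± 0.08 (adjusted p = 3.24e-14) in FLO1, and by -3.02 ± 0.08 (adjusted p = 6.17e-19) and -3.14 ± 0.08 (adjusted p = 3.75e-19) in OE33. These are falls of 7.85-fold and 5.36-fold in FLO1 and 8.14-fold and 8.80-fold in OE33. After ABS the falls were -2.79 and -2.445 in FLO1 and -2.82 and -2.965 in OE33. In shControl cells ABS moved APEX1 by -0.11 in FLO1 (adjusted p = 0.542, edgeR with Benjamini-Hochberg) and -0.13 in OE33 (adjusted p = 0.306), neither of which passed. FLO1 cells with shAPE1#3 kept more APEX1 than those with shAPE1#1, by 0.55 ± 0.08 (adjusted p = 9.59e-05, edgeR with Benjamini-Hochberg).

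**Figure D1:**
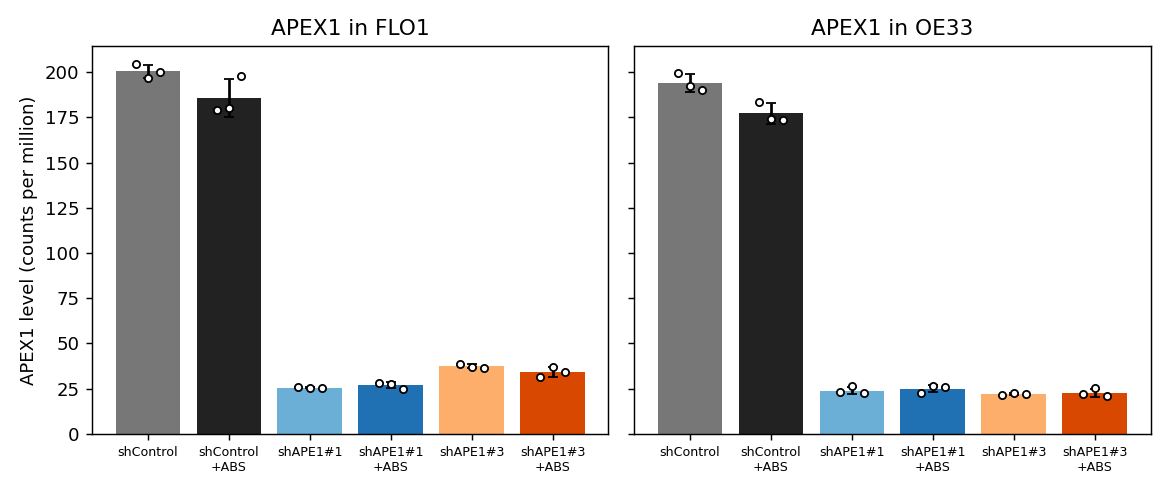
APEX1 in CPM for the 12 groups; bars are means, error bars SD and points the 3 libraries of each group. The level drops from 200.4 CPM in FLO1 shControl to 25.5 and 37.4 with the shRNAs, and from 193.9 CPM in OE33 shControl to 23.9 and 22.0.

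The next comparison asked how control cells respond to acidic bile salts. In FLO1 shControl cells the largest rises were in heat shock and immediate early genes. HSPA6 (ENSG00000173110; chromosome 1, 161524540 to 161526910, plus strand), a stress-inducible HSP70 gene, rose from 1.33 ± 0.347 to 29.7 ± 11.6 CPM, a log2 change of 4.49 ± 0.31. HSPA1A (ENSG00000204389; chromosome 6, 31815464 to 31817946, plus strand) rose from 116.6 ± 7.75 to 827.4 ± 80.3 CPM (2.83 ± 0.12), with HSPA1B at 2.68 ± 0.12 and the cochaperone DNAJB1 at 1.83 ± 0.09. The orphan nuclear receptor NR4A3 (ENSG00000119508; chromosome 9, 99821855 to 99866891, plus strand) rose from 2.39 ± 1.42 to 39.8 ± 5.48 CPM (4.07 ± 0.22), with NR4A1 at 2.99 ± 0.18 and NR4A2 at 2.275 ± 0.19. FOSB (2.30 ± 0.28), FOS (2.03 ± 0.21), EGR3 (2.00 ± 0.17), EGR1 (1.85 ± 0.10), the neuronal activity gene ARC (1.97 ± 0.16) and the small GTPase gene RRAD (2.00 ± 0.16) rose as well. Among the falls were the mitochondrial tRNA genes MT-TF (-1.79 ± 0.13), MT-TV (-1.425 ± 0.12) and MT-TQ (-0.86 ± 0.14), and ID1, a target of BMP signaling (-0.79 ± 0.09). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was at most 0.000665 for each of these genes.

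Of 24 measured immediate early and AP-1 genes in FLO1, 16 rose, 0 fell and 8 did not pass (17 rose when adjusted over the list alone; camera with Benjamini-Hochberg, adjusted p = 1.54e-48, and adjusted p = 0.000592 with an estimated correlation). ER chaperone and unfolded protein response genes followed, with 10 of 21 higher (14 over the list alone; camera adjusted p = 1.22e-31, and adjusted p = 0.000152 with an estimated correlation). They included DNAJB9 (1.36), HERPUD1 (1.35), MANF (1.16), SDF2L1 (1.05) and HSPA5, the chaperone BiP (ENSG00000044574; chromosome 9, 125234853 to 125241330, minus strand), at 1326 ± 26.2 CPM unexposed and 2727 ± 111 after ABS. In the heat shock list 6 of 18 rose and 1 fell (7 and 1 over the list alone; camera adjusted p = 2.54e-31, and adjusted p = 0.00103 with an estimated correlation). NF-kB targets were also called up, with 6 of 20 higher, NFKB2 at 0.96 among them (12 over the list alone; camera adjusted p = 2.4e-09, and adjusted p = 0.0275 with an estimated correlation). Cholesterol biosynthesis and uptake genes rose in 5 of 23, with STARD4 at 1.11 and HSD17B7 at 0.64 (7 over the list alone; camera adjusted p = 0.000356, and adjusted p = 0.0138 with an estimated correlation). Both STARD4 and HSD17B7 missed the threshold in a fit to only the groups compared.

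In FLO1 4 further lists lost their call with an estimated correlation. Mitosis genes were lower, with 5 of 25 called, such as CCNB1 at -0.46 (10 over the list alone; camera with Benjamini-Hochberg, adjusted p = 3.65e-11, and adjusted p = 0.0888 with an estimated correlation); CCNB1 missed the threshold in a fit to only the groups compared. Nuclear oxidative phosphorylation genes had 0 of 25 called and a median of -0.212 (camera adjusted p = 1.15e-05, and adjusted p = 0.452 with an estimated correlation). Of 24 p53 targets, 6 rose, GADD45A by 0.775, and 18 did not pass (6 higher and 1 lower over the list alone; camera adjusted p = 0.014 upward, against a median of -0.03, and adjusted p = 0.0624 with an estimated correlation). YAP and TEAD targets had 2 of 19 called, one of them ANKRD1 at 1.96 (4 over the list alone; camera adjusted p = 0.0349, and adjusted p = 0.322 with an estimated correlation), and that list call was lost without FLO1 shControl ABS replicate 2 (adjusted p = 0.272). The integrated stress response list was not called, with 3 higher and 1 lower of 22 and PPP1R15A at 0.75 (camera adjusted p = 0.854). Hypoxia targets were not called either, with 2 of 23 higher, ANGPTL4 at 1.04 among them (camera adjusted p = 0.709).

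In all, 419 genes rose and 87 fell in FLO1 shControl cells after ABS, 506 of 16868 tested, 127 of them by at least 2-fold (edgeR quasi-likelihood test with Benjamini-Hochberg). The count was sensitive to single libraries: it was 306 and 287 without shControl replicates 1 and 2, and 918 and 923 without shControl ABS replicates 1 and 2. It was 102 in a fit to only the groups compared, 807 with DESeq2 and 1491 with a GC correction. The balance moved as well, from 98 higher and 4 lower in a fit to only the groups compared to 601 and 322 without shControl ABS replicate 2.

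OE33 shControl cells were asked the same question. The aldo-keto reductase gene AKR1C1 (ENSG00000187134; chromosome 10, 4963253 to 4983283, plus strand), an NRF2 target, rose from 4.10 ± 0.465 to 12.8 ± 2.34 CPM (1.65 ± 0.15). The mucin gene MUC5AC (ENSG00000215182; chromosome 11, 1157953 to 1201138, plus strand) rose from 9.0 ± 0.151 to 24.5 ± 1.14 CPM (1.44 ± 0.18), and MUC13 rose by 1.63 ± 0.21. CYP1A1, a target of the aryl hydrocarbon receptor, rose by 1.22 ± 0.09, the interferon-stimulated gene OAS1 by 1.15 ± 0.08, the syntenin-related SDCBP2 by 1.32 ± 0.10 and FOSB by 1.53 ± 0.19. HSPA6 fell in this line, from 14.2 ± 0.808 to 6.92 ± 0.387 CPM (-1.035 ± 0.13), as did HSPA1A, from 316.7 ± 8.66 to 232.0 ± 16.1 CPM (-0.45). The sterol synthesis genes MSMO1 (-0.86 ± 0.13) and MVK (-0.77 ± 0.08) fell, as did ID1 (-0.75 ± 0.07) and ID3 (-0.85 ± 0.11). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment each of these genes had an adjusted p of at most 0.000428.

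ER chaperone and unfolded protein response genes rose in OE33 too: 12 of 21, with HSPA5 going from 624.1 ± 14.5 to 1303 ± 22.6 CPM and HYOU1 at 0.78 (13 higher and 1 lower over the list alone; camera with Benjamini-Hochberg, adjusted p = 5.27e-16, and adjusted p = 0.00138 with an estimated correlation). NRF2 targets rose in 11 of 24, including GCLM (0.66) and SQSTM1 (0.645) (15 over the list alone; camera adjusted p = 1.22e-12, and adjusted p = 0.00273 with an estimated correlation). In the cholesterol list 10 of 24 fell, with HMGCS1 at -0.66 (16 over the list alone; camera adjusted p = 1.02e-13, and adjusted p = 0.00163 with an estimated correlation). DNA replication genes fell in 10 of 28, GINS2 at -0.44 and MCM6 at -0.41 (15 over the list alone; camera adjusted p = 1.96e-09, and adjusted p = 0.00538 with an estimated correlation). Heat shock genes fell in 6 of 17 and rose in 1 (10 and 1 over the list alone; camera adjusted p = 1.35e-08, and adjusted p = 0.012 with an estimated correlation), HSPA8 at -0.52 among them. NF-kB targets rose in 8 of 20 and fell in 1 (11 and 1 over the list alone; camera adjusted p = 8.68e-09, and adjusted p = 0.0399 with an estimated correlation), with NFKB2 at 0.77 and IL1B at -1.605. Columnar and intestinal genes rose in 4 of 15, AGR2 (0.60) and SOX9 (0.44) beside the 2 mucins (4 over the list alone; camera adjusted p = 0.00113, and adjusted p = 0.0469 with an estimated correlation).

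Base excision repair genes, the pathway APE1 belongs to, were lower in OE33 after ABS, with 2 of 23 called, UNG at -0.45 and NEIL2 at -0.41 (2 over the list alone; camera with Benjamini-Hochberg, adjusted p = 0.000178, and adjusted p = 0.0399 with an estimated correlation). In FLO1 0 of 23 were called (camera adjusted p = 0.854). Homologous recombination and Fanconi genes fell in 2 of 25, BLM at -0.41 and FANCI at -0.27 (3 over the list alone; camera adjusted p = 0.000234, and adjusted p = 0.415 with an estimated correlation). Lysosome and autophagy genes rose in 8 of 22, GABARAPL1 at 0.94 and NPC1 at 0.46 (8 and 1 lower over the list alone; camera adjusted p = 0.000278, and adjusted p = 0.0586 with an estimated correlation). Interferon-stimulated genes rose in 6 of 27, STAT2 (0.52) and OAS3 (0.47) with OAS1 (camera adjusted p = 0.000268, and adjusted p = 0.0607 with an estimated correlation). Mitochondrially encoded genes rose in 6 of 13, MT-ND4L at 0.46 (camera adjusted p = 6.91e-06, and adjusted p = 0.159 with an estimated correlation). YAP and TEAD targets rose in 6 of 18, IGFBP3 and AMOTL2 at 0.51 each (camera adjusted p = 1.33e-05, and adjusted p = 0.0887 with an estimated correlation).

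Further OE33 lists were called in camera with Benjamini-Hochberg adjustment and lost with an estimated correlation. For the integrated stress response, 7 of 20 genes rose, ATF4 at 0.51, and 2 fell (adjusted p = 0.000524, and adjusted p = 0.129 with an estimated correlation). For epithelial genes 5 of 24 rose, DSP at 0.51, and 1 fell (adjusted p = 0.00125, and adjusted p = 0.234 with an estimated correlation). Immediate early and AP-1 genes rose in 7 of 24, ATF3 at 1.14, and fell in 2, IER3 at -0.41 (adjusted p = 0.00422, and adjusted p = 0.305 with an estimated correlation). Mesenchymal genes rose in 3 of 14, FN1 at 0.62 (adjusted p = 0.0182, and adjusted p = 0.341 with an estimated correlation), and nuclear oxidative phosphorylation genes had 0 of 25 called (adjusted p = 0.00388, and adjusted p = 0.677 with an estimated correlation). Squamous genes were not called, with KRT6A (0.835) the 1 riser of 17 (camera adjusted p = 0.0957).

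In OE33 916 genes rose and 390 fell, 1306 of 15540, 86 of them by at least 2-fold (edgeR quasi-likelihood test with Benjamini-Hochberg). Without shControl replicates 1 and 2 the count was 799 and 683, and without shControl ABS replicates 1, 2 and 3 it was 858, 760 and 759. A fit to only the groups compared called 2157, and a GC correction 2365. The balance ranged from 543 higher and 140 lower without shControl replicate 2 to 1352 and 1013 with a GC correction.

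**Figure D2:**
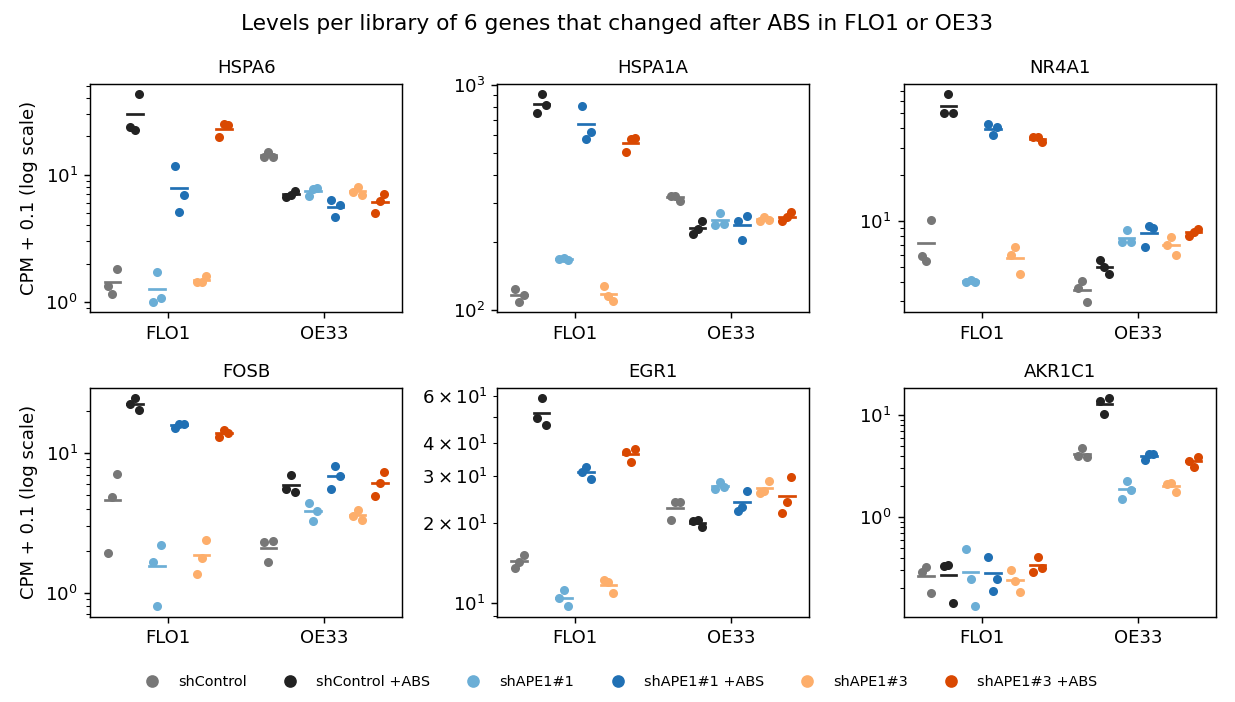
CPM plus 0.1 on a log scale for HSPA6, HSPA1A, NR4A1, FOSB, EGR1 and AKR1C1 in the 12 groups; points are libraries and lines group means. HSPA6 rises from 1.33 to 29.7 CPM in FLO1 shControl cells after ABS and falls from 14.2 to 6.92 CPM in OE33 shControl cells.

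Whether the 2 lines responded differently to ABS was tested as the difference of their responses, OE33 minus FLO1; culture medium differed with the line. Heat shock and immediate early genes responded lower in OE33: HSPA6 by -5.53 ± 0.34 (adjusted p = 1.13e-14), HSPA1A by -3.285 ± 0.15 (adjusted p = 1.24e-18), DNAJB1 by -2.25 ± 0.11 (adjusted p = 9.75e-18), NR4A1 by -2.49 ± 0.26 (adjusted p = 2.13e-08) and EGR1 by -2.045 ± 0.15 (adjusted p = 1.08e-12, edgeR quasi-likelihood test with Benjamini-Hochberg). MT-TF differed by 2.03 ± 0.16, since it fell in FLO1. By list, 5 heat shock genes and 10 cholesterol genes responded lower in OE33 (camera with Benjamini-Hochberg, adjusted p = 2.01e-56 and 8.07e-23, and adjusted p = 5.28e-08 and 5.73e-08 with an estimated correlation). Of the genes that differed, 139 were higher and 176 lower in OE33, 315 of 18199. The count was 887 without FLO1 shControl ABS replicate 2 and 202 without OE33 shControl ABS replicate 3, 592 with DESeq2, 951 with a GC correction and 99 in a fit to only the groups compared. The balance turned in some of these, to 569 higher and 318 lower without FLO1 shControl ABS replicate 2, 324 and 268 with DESeq2, 484 and 467 with a GC correction, and 184 and 173 without a filter. Over 14132 genes tested in both lines the 2 responses correlated at 0.16, and 107 genes were called in both with 1 sign, 100 higher (21.9 by chance) and 7 lower (2.03 by chance), against 15 with opposite signs (14.1 by chance).

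The same exposure was then examined in APE1-depleted cells, counting genes called with both shRNAs. In FLO1 NR4A3 rose by 4.815 and 4.07 with shAPE1#1 and shAPE1#3, FOSB by 3.415 and 3.025, NR4A1 by 3.33 and 2.57, HSPA6 by 2.73 and 4.055, HSPA1A by 1.99 and 2.23, and EGR1 by 1.57 and 1.63. MT-TF fell by -0.95 and -1.88, MT-TV by -0.875 and -1.52, and TGFBR3, a TGF-beta coreceptor, by -0.53 and -0.575. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 162 genes rose and 30 fell with both shRNAs, 192 in all, 39 of them by at least 2-fold, from 845 with shAPE1#1 and 306 with shAPE1#3. Of the 506 genes called in shControl cells, 173 were called here with 1 sign (153 higher and 20 lower, with 4.02 and 0.155 by chance). Immediate early and AP-1 genes were called up, 12 of 24 (14 over the list alone; camera with Benjamini-Hochberg, adjusted p = 3.34e-64, and adjusted p = 0.000205 with an estimated correlation). ER chaperone genes rose in 8 of 21, DNAJB9 by 1.21 and 1.04 (9 over the list alone; camera adjusted p = 7.47e-29, and adjusted p = 0.000172 with an estimated correlation). Heat shock genes rose in 5 of 18 and fell in 1 (camera adjusted p = 1.36e-29, and adjusted p = 0.00128 with an estimated correlation). NF-kB (3 of 20, NFKB2 at 0.68 and 0.86), cholesterol (2 of 23, STARD4 at 0.875 and 1.01) and p53 targets (5 of 24, GADD45A at 0.78 and 0.71) were also called up (camera adjusted p = 1.17e-11, 1.37e-05 and 0.000957, and adjusted p = 0.0138, 0.00511 and 0.016 with an estimated correlation). The gene count was 456 without shControl ABS replicate 2, a library outside these groups that enters through the pooled spread, and 123, 123 and 125 without shAPE1#3 replicates 1, 2 and 3. It was 308 with DESeq2, 678 with a GC correction and 553 in a fit to only the groups compared.

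In APE1-depleted OE33 cells CYP1A1 rose by 1.09 and 1.49 after ABS, the aryl hydrocarbon receptor repressor gene AHRR by 0.915 and 0.97, SDCBP2 by 1.02 and 0.97, HSPA5 by 1.07 and 0.86, and OAS1 by 0.95 and 0.835. ID3 fell by -0.87 and -0.62, ID1 by -0.66 and -0.61, DDIT3 by -0.63 and -0.56, and the cytokine gene LIF by -0.48 and -0.43. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 199 genes rose and 54 fell with both shRNAs, 253 in all, 2 of them by at least 2-fold, from 735 and 351; 230 were also called in shControl cells with 1 sign (184 and 46, with 11.7 and 1.36 by chance). ER chaperone genes rose in 9 of 21 (12 over the list alone; camera with Benjamini-Hochberg, adjusted p = 5.42e-26, and adjusted p = 0.000236 with an estimated correlation), interferon-stimulated genes in 6 of 27, OAS3 by 0.55 and 0.44 (9 over the list alone; camera adjusted p = 1.47e-10, and adjusted p = 0.00538 with an estimated correlation), and NRF2 targets in 6 of 24, GCLM by 0.51 and 0.44 (8 over the list alone; camera adjusted p = 8.58e-08, and adjusted p = 0.012 with an estimated correlation). Columnar genes rose in 3 of 15, AGR2 by 0.58 and 0.44 (camera adjusted p = 6.9e-09, and adjusted p = 0.00273 with an estimated correlation). Cholesterol genes fell in 4 of 24, HMGCS1 by -0.54 and -0.37 (camera adjusted p = 8.68e-09, and adjusted p = 0.00599 with an estimated correlation), and DNA replication genes in 2 of 28 (camera adjusted p = 1.18e-05, and adjusted p = 0.0307 with an estimated correlation). The gene count was 156 without shAPE1#1 replicate 3, 122, 117 and 152 without shAPE1#3 replicates 1, 2 and 3, and 116 without shAPE1#3 ABS replicate 3. It was 473 with DESeq2, 556 with a GC correction and 143 in a fit to only the groups compared.

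Next came the effect of APE1 knockdown in unexposed cells. In FLO1 few genes moved with both shRNAs. KIAA0319 rose by 0.82 ± 0.10 and 0.85 ± 0.10 and ZNF697, a zinc finger gene, fell by -0.54 ± 0.09 and -0.58 ± 0.09 with shAPE1#1 and shAPE1#3; neither lost its call in any alternative. CHAC1 (ENSG00000128965; chromosome 15, 40952962 to 40956519, plus strand), an ATF4 target that degrades glutathione, fell from 40.6 ± 5.65 to 19.1 ± 0.441 and 27.8 ± 1.09 CPM. RBM38 (ENSG00000132819; chromosome 20, 57391407 to 57409333, plus strand), an RNA-binding p53 target, read 97.0 ± 8.36, 71.1 ± 4.07 and 49.96 ± 1.77 CPM. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment 12 genes were called with both shRNAs, 5 higher (KIAA0319, PADI2, KCNK6, TDRD10 and LINC02995) and 7 lower (APEX1, CHAC1, ZNF697, SMIM32, RBM38, TGFBI and FOSB), 3 of them by at least 2-fold. TDRD10 and LINC02995 are named because the count is small, after the values were seen. RBM38 missed the threshold with shAPE1#1 when any shControl or shAPE1#1 library was left out (adjusted p of up to 0.183), and CHAC1 did so with shAPE1#3 without shControl replicate 1 or 3 or any shAPE1#3 library (adjusted p of up to 0.196). SMIM32, TGFBI, KCNK6 and FOSB each missed it without several single libraries, and PADI2 without shAPE1#3 replicate 2 (adjusted p = 0.0507). With shAPE1#1 763 genes rose and 374 fell, and with shAPE1#3 28 rose and 105 fell. Without single libraries the count of 12 was 7 (shControl replicate 2), 6 (shControl replicate 3), 57 (shControl ABS replicate 2), 6 (shAPE1#1 replicate 1) and 4 (each of shAPE1#3 replicates 1, 2 and 3). It was 33 with DESeq2, 28 without a filter, 91 with a GC correction, 101 in a fit to only the groups compared and 6 with a replicate block. More genes were higher than lower in several of these, 31 and 26 without shControl ABS replicate 2 and 58 and 43 in a fit to only the groups compared.

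In FLO1 the integrated stress response list was lower with knockdown, with CHAC1 the 1 of 22 genes called with both shRNAs, 14 lower with shAPE1#1 and 2 lower with shAPE1#3 (camera on the mean of both shRNAs with Benjamini-Hochberg, adjusted p = 1.25e-14, and adjusted p = 0.00178 with an estimated correlation). Cholesterol genes were higher as a list, with 0 of 23 called with both shRNAs (camera adjusted p = 0.00347, and adjusted p = 0.0362 with an estimated correlation). This is a mean of both shRNAs, and the list stood lower with shAPE1#3 than with shAPE1#1. NF-kB targets were lower, 0 of 20 called with both (camera adjusted p = 1.3e-05, and adjusted p = 0.0858 with an estimated correlation). Base excision repair genes had 0 of 23 called (camera adjusted p = 0.449). Both shRNAs were set against the same shControl libraries. The 12 shared calls compare with 1.27 higher and 2.33 lower by chance, and 32 genes were called with opposite signs (5.37 by chance). The 2 effects had a covariance of 0.0407, against 0.0378 in simulations without an effect, where the mean number of shared calls was 0. The shRNAs' correlation was 0.283, and 0.508 in those simulations. They drew each gene on its own, while the spread of the real libraries is partly shared between genes. The simulated number of shared calls may therefore be lower than what chance gives in these libraries.

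In OE33 the knockdown moved many genes. ALDH3A1 (ENSG00000108602; chromosome 17, 19737984 to 19748943, minus strand), an aldehyde dehydrogenase gene, fell from 110.5 ± 8.21 to 12.7 ± 1.18 and 13.7 ± 0.816 CPM (-3.12 ± 0.10 and -3.01 ± 0.10; adjusted p = 1.02e-17 and 2.81e-17, edgeR quasi-likelihood test with Benjamini-Hochberg). The interferon-induced gene IFI27 (ENSG00000165949; chromosome 14, 94104836 to 94116698, plus strand) fell from 16.25 ± 3.59 to 2.36 ± 0.453 and 2.14 ± 0.976 CPM (-2.775 and -2.90). The netrin receptor gene UNC5B fell by -2.62 and -2.72, the circadian repressor gene BHLHE41 by -2.50 and -2.59, and the potassium channel gene KCNQ1 by -2.05 and -2.04. HPGD (ENSG00000164120; chromosome 4, 174490177 to 174523154, minus strand), which degrades prostaglandins, rose by 2.11 ± 0.10 and 2.10 ± 0.10. MYL9 (ENSG00000101335; chromosome 20, 36541484 to 36551447, plus strand), a myosin light chain gene, rose by 2.23 and 2.36, the muscle ubiquitin ligase gene FBXO32 by 2.05 and 2.07, the activin subunit gene INHBA by 2.01 and 1.96, and SERPINE2 by 1.94 and 2.10. VIM read 0.574 ± 0.24, 5.71 ± 2.19 and 3.23 ± 0.277 CPM, a low level against 3124 ± 191 in FLO1 shControl. The knockdown libraries held 0.159% of its FLO1 level, so reads carried over from FLO1 libraries are a candidate explanation for its rise.

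Interferon-stimulated genes fell in 14 of 27 in OE33, with IFI6 at -1.785 and -2.015 and BST2 at -1.34 and -2.12 (1 higher and 14 lower over the list alone; camera with Benjamini-Hochberg, adjusted p = 5.99e-16, and adjusted p = 0.00163 with an estimated correlation). Squamous and keratinocyte genes rose in 9 of 17, SPRR1B by 2.14 and 1.92, KRT13 by 1.375 and 1.23 and KRT6A by 1.13 and 1.16 (9 over the list alone; camera adjusted p = 1.2e-07, and adjusted p = 0.0203 with an estimated correlation). NRF2 targets fell in 10 of 24 and rose in 4, with the aldo-keto reductase genes AKR1B10 at -2.99 and -3.15, AKR1C1 at -1.22 and -1.105 and AKR1C3 at -1.01 and -1.19 (11 lower and 4 higher over the list alone; camera adjusted p = 0.00825, and adjusted p = 0.153 with an estimated correlation). Immediate early and AP-1 genes rose in 6 of 24 and fell in 1, ATF3 at 1.83 and 1.58 and DUSP1 at 1.15 and 1.13 (8 and 1 over the list alone; camera adjusted p = 2.83e-05, and adjusted p = 0.116 with an estimated correlation). Heat shock genes fell in 7 of 17, HSPA1A at -0.34 and -0.32 (camera adjusted p = 0.000517, and adjusted p = 0.0827 with an estimated correlation). Targets of p53 fell in 5 of 24 and rose in 1, with GDF15 at -0.85 and -0.92 and CDKN1A at -0.79 and -0.86 (6 and 3 over the list alone; camera adjusted p = 0.0449, and adjusted p = 0.0921 with an estimated correlation).

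Other OE33 lists moved with knockdown in both directions. Lysosome and autophagy genes rose in 6 of 22, NEU1 at 0.70 and 0.71, and fell in 2, CTSD at -0.79 and -0.72 (camera with Benjamini-Hochberg, adjusted p = 0.00934, and adjusted p = 0.154 with an estimated correlation). NF-kB targets rose in 8 of 20, CXCL3 at 1.17 and 0.90, and fell in 2, TNFAIP2 at -1.03 and -0.98 and CXCL8 at -0.83 and -0.86 (camera adjusted p = 0.0277, and adjusted p = 0.416 with an estimated correlation). YAP and TEAD targets rose in 7 of 18, CCN1 at 0.82 and 0.87, and fell in 3 (camera adjusted p = 0.0414, and adjusted p = 0.455 with an estimated correlation). Mesenchymal genes rose in 4 of 14, FN1 at 1.01 and 1.39 and ITGA5 at 1.17 and 1.33, and fell in 2 (camera adjusted p = 0.0224, and adjusted p = 0.357 with an estimated correlation). The list holds VIM and was not tested again without genes at the level of reads that may be carried over from FLO1. Lists not called were hypoxia (2 higher and 4 lower, ANGPTL4 at -1.13 and -1.002; camera adjusted p = 0.0841), columnar genes (1 higher and 3 lower, MUC5AC at -1.51 and -1.49; adjusted p = 0.253), epithelial genes (1 higher and 4 lower, KRT19 at -0.50 and -0.50; adjusted p = 0.308) and base excision repair (1 higher, LIG3 at 0.21 and 0.21, which missed the threshold in other settings; camera adjusted p = 0.772).

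With both shRNAs 1033 genes rose and 971 fell in OE33, 2004 in all, 286 of them by at least 2-fold (edgeR quasi-likelihood test with Benjamini-Hochberg). The single shRNAs gave 2544 and 3367 calls, and 0 genes were called with opposite signs. Between the 2 shRNA groups edgeR called 0 genes. Whether both groups carry the same hairpin could not be decided, so their agreement may not be that of 2 hairpins. Independent lists of these sizes would share 143 and 133 genes by chance, and part of the excess over these values may come from the shared controls, which cannot be divided between the shRNAs. The covariance of the 2 effects was 0.1773, against 0.0286 in simulations with only the shared controls, which gave 0 shared calls, and the correlation was 0.794 against 0.48. Only the spread between libraries was simulated, for each gene on its own, so a spread that genes share was left out. A shift of all shControl libraries would enter both effects alike and cannot be told apart from knockdown here. The balance turned to 854 higher and 985 lower without a filter, and was 1464 and 1469 with a GC correction. Between the lines, 2 genes were called with both shRNAs in 1 direction in both, APEX1 among them, 1 higher (0.199 by chance) and 1 lower (0.367 by chance), and 2 with opposite signs (0.581 by chance). With shAPE1#1 alone 142 genes were higher in both lines (51.1 by chance), 110 lower (25.8 by chance) and 95 opposite (76.4 by chance). With shAPE1#3 alone 4 were higher (2.6 by chance), 7 lower (9.45 by chance) and 36 opposite (12.6 by chance).

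Knockdown was compared again after ABS. In FLO1 the heat shock gene DNAJB1 was lower by -0.615 and -0.54 with shAPE1#1 and shAPE1#3, HSPA1B by -0.49 and -0.65, EGR1 by -0.74 and -0.51, and RBM38 by -0.67 and -1.001, while KIAA0319 was higher by 0.57 and 0.76. In a fit to only the groups compared DNAJB1, HSPA1B and EGR1 missed the threshold with shAPE1#3, and EGR1 also did so without shAPE1#3 ABS replicate 2 (adjusted p = 0.084, edgeR with Benjamini-Hochberg). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 24 genes were called with both shRNAs, 8 higher and 16 lower, 6 of them by at least 2-fold, against 40 called with opposite signs. By chance these would be 1.73, 9.23 and 10.9. Covariance was 0.0599, with 0.0384 in the shared-control simulations, which gave at most 1 shared call. Those drew each gene on its own, so chance may give more shared calls in the real libraries. The integrated stress response list was again lower, with 13 of 22 genes lower with shAPE1#1 and 1 with both (camera with Benjamini-Hochberg, adjusted p = 1.09e-10, and adjusted p = 0.00592 with an estimated correlation). Heat shock genes were lower in 2 of 18 (camera adjusted p = 0.000464, and adjusted p = 0.212 with an estimated correlation), and cholesterol genes were higher as a list (adjusted p = 0.00618, and adjusted p = 0.0486 with an estimated correlation). The cholesterol call is on the mean of both shRNAs, which differed in that list in unexposed cells. The gene count was 39, 142 and 15 without shControl ABS replicates 1, 2 and 3, 15 without shAPE1#1 ABS replicate 2, and 15, 10 and 11 without shAPE1#3 ABS replicates 1, 2 and 3. It was 48 with DESeq2, 41 without a filter, 116 with a GC correction and 7 in a fit to only the groups compared. The balance turned to 90 higher and 52 lower without shControl ABS replicate 2, 22 and 19 without a filter, and 4 and 3 in a fit to only the groups compared.

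In OE33 after ABS ALDH3A1 was lower by -2.88 with each shRNA, BHLHE41 by -2.67 and -2.37, AKR1C1 by -1.725 and -1.92 and the sulfatase gene SULF2 by -2.14 and -1.91. HPGD was higher by 1.96 and 1.94, MYL9 by 2.06 and 2.27, and the keratinocyte envelope gene SPRR2D by 2.66 and 2.66. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 893 genes were higher and 1029 lower with both shRNAs, 1922 in all, 242 of them by at least 2-fold, and 1330 of them were also called in unexposed cells (637 and 693, with 59.4 and 64.3 by chance). Covariance of the 2 effects was 0.1517, with 0.0272 in the shared-control simulations, which gave 0 shared calls and drew each gene on its own. As for unexposed cells, whether both groups carry the same hairpin could not be decided. NRF2 targets were lower in 12 of 24 and higher in 4, AKR1C3 at -1.575 and -1.465 (14 and 4 over the list alone; camera with Benjamini-Hochberg, adjusted p = 3.47e-07, and adjusted p = 0.0189 with an estimated correlation). Interferon-stimulated genes were lower in 13 of 27 (14 over the list alone; camera adjusted p = 1.26e-13, and adjusted p = 0.00273 with an estimated correlation) and squamous genes higher in 8 of 17 (9 over the list alone; camera adjusted p = 6.91e-06, and adjusted p = 0.0399 with an estimated correlation). Cholesterol genes were higher in 6 of 24, SQLE at 0.51 and 0.64 (camera adjusted p = 0.017, and adjusted p = 0.164 with an estimated correlation). Integrated stress response genes were lower in 6 of 20, ATF4 at -0.48 and -0.50 and PHGDH at -0.74 and -0.71, and higher in 2 (camera adjusted p = 0.237).

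The question at the centre of the series, whether the response to ABS depends on APE1, is answered by the interaction of knockdown and exposure. No gene passed with both shRNAs in either line: edgeR's quasi-likelihood test with Benjamini-Hochberg called 0 genes in FLO1 and 0 in OE33. At an unadjusted p under 0.05 with both shRNAs, 127 and 191 genes had 1 sign, and DESeq2 called 1 and 4. In FLO1 the 1 gene was HSPA1B, chosen here after the values were seen, at -0.775 and -0.834 in DESeq2. HSPA1B went from 54.7 ± 6.28 to 349.6 ± 30.6 CPM in FLO1 shControl cells, from 66.35 ± 3.17 to 249.2 ± 41.7 CPM with shAPE1#1 and from 62 ± 3.06 to 222.7 ± 12.1 CPM with shAPE1#3. In OE33 the 4 genes, also named after the values were seen, were CYP24A1, DKK1, UPK1B and CD55. CD55, a complement regulator, went from 98.9 to 169.3 CPM in shControl cells and from 137.7 to 177.7 and 139.6 to 180.1 CPM with the shRNAs. With shAPE1#3 alone 2 genes passed in OE33, TSPAN8 by 1.35 ± 0.20 (adjusted p = 0.00475, edgeR with Benjamini-Hochberg) and TFF2, from 0.0627 to 6.18 ± 2.29 CPM. A filter left off called 3 genes in each line, HSPA1B, KRT17 and KRT6A in FLO1 and CLDN18, FN1 and FBN2 in OE33. In FLO1 shControl KRT17 read 9.46 ± 13 and KRT6A 2.06 ± 3.38 CPM, each with an SD above the mean. FBN2 went from 0.0736 ± 0.0999 to 1.19 ± 1.21 CPM in OE33 shControl cells. CLDN18 reached at most 2.40 ± 0.55 CPM in OE33, with shAPE1#3 after ABS. A GC correction called 1 in FLO1, again HSPA1B, and 2 in OE33, CD55 again and LAMB3. These too are named after the values were seen. Without FLO1 shAPE1#1 ABS replicate 1 the count was 1. In simulated data the interaction test recovered 76.0% (FLO1) and 86.0% (OE33) of 2-fold changes and 11.5% and 45.5% of 1.5-fold changes, so smaller dependences on APE1 are not ruled out. Those simulated genes had a mean log2 CPM above 1 and no spread shared between genes, so recovery in the real libraries may be lower.

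By list, the mean interaction of both shRNAs passed in OE33 for mitochondrially encoded genes (median -0.228), mesenchymal genes (-0.324), the integrated stress response (-0.148) and cholesterol genes (0.075). Camera with Benjamini-Hochberg gave adjusted p = 1.69e-13, 6.03e-07, 8.4e-07 and 3.05e-05, and adjusted p = 0.0371, 0.0468, 0.0434 and 0.0335 with an estimated correlation. The mesenchymal list holds VIM and was not tested again without genes at the level of reads that may be carried over from FLO1. Another 10 lists were called in OE33 at the preset correlation alone, among them heat shock (adjusted p = 5.53e-05, and adjusted p = 0.0523 with an estimated correlation), NRF2 targets (adjusted p = 0.000278, and adjusted p = 0.0598 with an estimated correlation) and base excision repair (adjusted p = 0.0015, and adjusted p = 0.0695 with an estimated correlation). In FLO1 7 lists were called and 0 with an estimated correlation. They included heat shock, called lower against a median of 0.009 (camera adjusted p = 0.0153, and adjusted p = 0.421 with an estimated correlation), and nuclear oxidative phosphorylation, called higher (adjusted p = 2.78e-08, and adjusted p = 0.335 with an estimated correlation).

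The difference between lines in the knockdown effect was tested as for ABS. UNC5B (-2.92 ± 0.20), BHLHE41 (-2.59 ± 0.19), PLXNA2 (-2.34 ± 0.29), CALB2 (-2.24 ± 0.14) and IFI6 (-1.996 ± 0.17) had lower effects in OE33 than in FLO1, each with an adjusted p of at most 5.94e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg. Interferon-stimulated genes differed as a list, with 11 of them lower in OE33 (camera with Benjamini-Hochberg, adjusted p = 7.18e-15, and adjusted p = 2.09e-06 with an estimated correlation). Integrated stress response genes differed the other way, with 8 higher (camera adjusted p = 6.01e-08, and adjusted p = 0.00386 with an estimated correlation). The test was 1 contrast on the mean of both shRNAs and was not limited to genes called with both. In FLO1 that mean joins unlike effects, since the shRNAs differed there in 2054 genes and in both of these lists. Integrated stress response genes fell in FLO1 mostly with shAPE1#1. In all 499 genes were higher and 660 lower in OE33, 1159 of 18199 (564 higher and 552 lower without a filter), and 1847 in a fit to only the groups compared or 2367 with a GC correction.

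**Figure D3:**
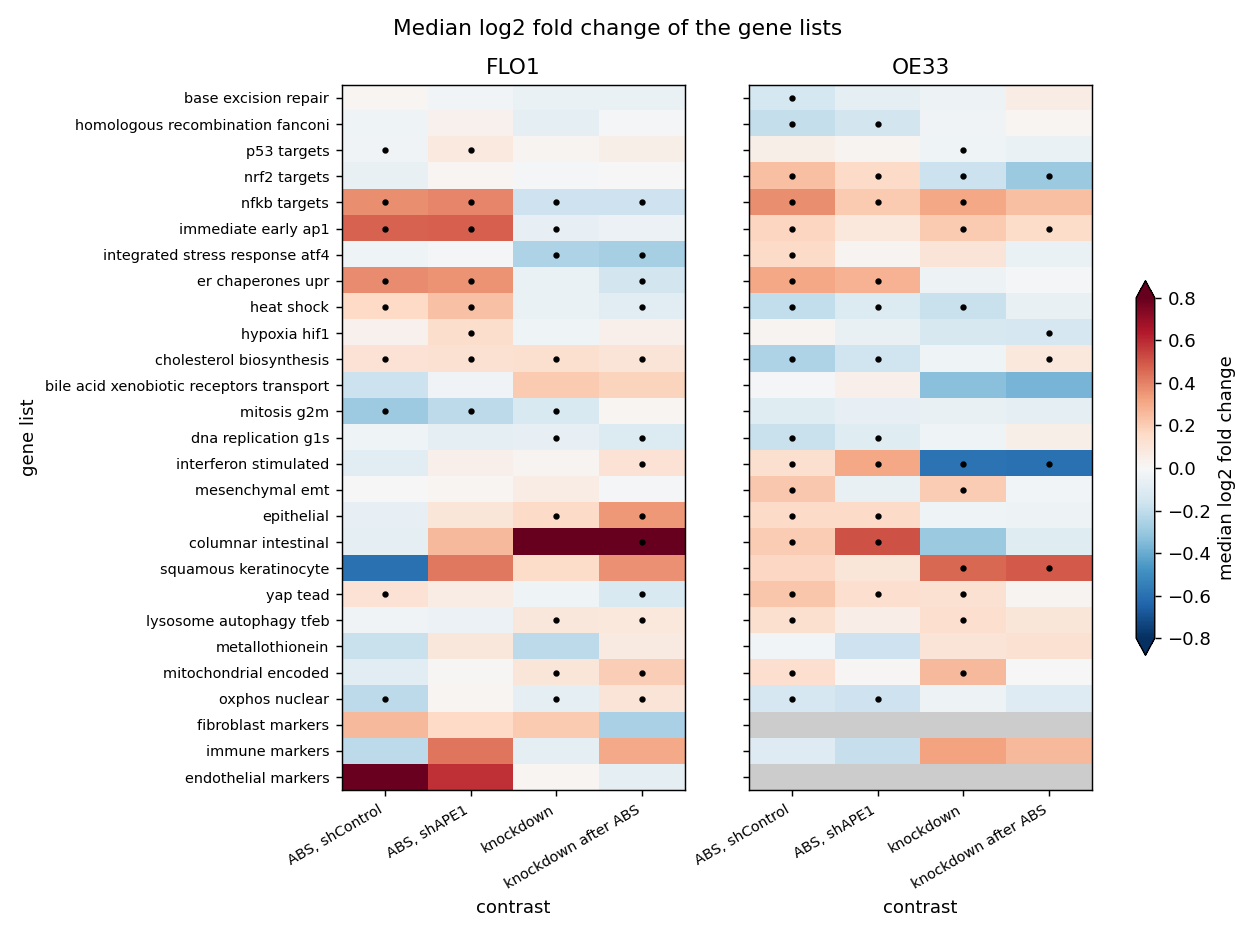
Median log2 fold change of the 27 gene lists for ABS in shControl cells, ABS in shAPE1 cells, knockdown, and knockdown after ABS in each line; colour saturates at 0.8 either way, dots mark camera adjusted p under 0.05 and grey means not tested. Interferon-stimulated genes are lower with knockdown in OE33 (median -0.59), and AP-1 genes are higher after ABS in FLO1 (median 0.471).

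Last, the 2 shRNAs were set against each other in unexposed cells, shAPE1#3 minus shAPE1#1. In FLO1 the carboxypeptidase gene CPA4 (ENSG00000128510; chromosome 7, 130293134 to 130324180, plus strand) read 4.20 ± 0.50 CPM in shControl, 17.9 ± 1.72 with shAPE1#1 and 2.37 ± 0.0701 with shAPE1#3, a difference of -2.92 ± 0.14 (adjusted p = 6.32e-12, edgeR quasi-likelihood test with Benjamini-Hochberg). PLAT, tissue plasminogen activator, differed by -2.83 ± 0.13, the glucose transporter gene SLC2A3 by -2.70 and EPAS1, which encodes HIF2A, by -1.98. CYP24A1 (ENSG00000019186; chromosome 20, 54153449 to 54173973, minus strand), a target of the vitamin D receptor, read 5.31 CPM in shControl, 2.99 ± 0.648 with shAPE1#1 and 12.6 ± 0.286 with shAPE1#3 (2.07 ± 0.18). SERBP1 (ENSG00000142864; chromosome 1, 67407810 to 67430415, minus strand), an mRNA-binding protein gene, read 622.8 ± 46.3, 282.2 ± 7.50 and 633.3 ± 45.6 CPM (1.17 ± 0.11). Interferon-stimulated genes were lower with shAPE1#3 in 12 of 25, OASL at -1.17 and IFIT2 at -1.13 (camera with Benjamini-Hochberg, adjusted p = 2.91e-07, and adjusted p = 0.0012 with an estimated correlation). Integrated stress response genes were higher in 11 of 22, PHGDH at 0.68 and PCK2 at 0.58, and lower in 1, NUPR1 at -1.655 (camera adjusted p = 1.57e-05, and adjusted p = 0.0486 with an estimated correlation). DNA replication genes were higher in 6 of 28 and cholesterol genes lower in 5 of 23, MSMO1 at -0.72 (camera adjusted p = 0.000644 and 0.00412, and adjusted p = 0.0435 and 0.041 with an estimated correlation). Mesenchymal genes were lower in 8 of 16, MMP2 at -1.35 and THBS1 at -0.98, and higher in 1 (camera adjusted p = 1.08e-05, and adjusted p = 0.125 with an estimated correlation).

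In FLO1 786 genes were higher and 1268 lower with shAPE1#3 than with shAPE1#1, 2054 in all, 360 of them by at least 2-fold (edgeR quasi-likelihood test with Benjamini-Hochberg). The count was 3437 without shControl ABS replicate 2, 1323 and 1321 without shAPE1#1 replicates 2 and 3, and 1338 and 1336 without shAPE1#3 replicates 1 and 2. It was 5428 in a fit to only the groups compared and 3741 with a GC correction. In OE33 edgeR called 0 genes, against 1248 at an unadjusted p under 0.05 and 34 with DESeq2. The edgeR count of 0 was 27 without shAPE1#1 replicate 1, 115 without a filter, 27 in a fit to only the groups compared and 12 with a GC correction. As a list, mitochondrially encoded genes were higher with shAPE1#3 in OE33 (median 0.286, 0 of 13 called and 10 over the list alone; camera with Benjamini-Hochberg, adjusted p = 1.63e-20, and adjusted p = 0.0117 with an estimated correlation).

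**Figure D4:**
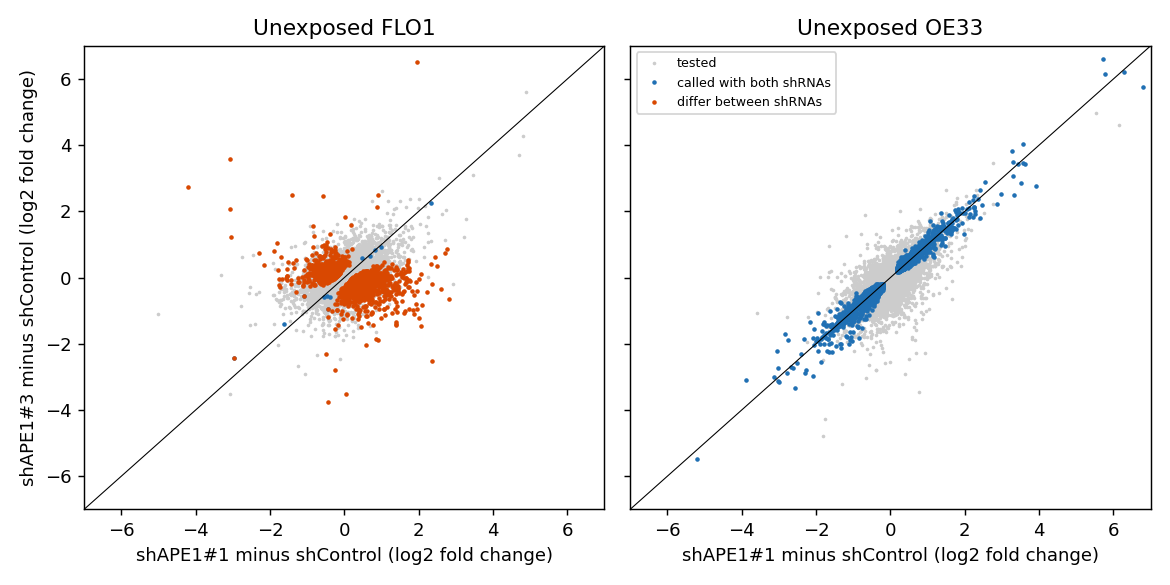
Log2 fold change with shAPE1#1 (horizontal) against shAPE1#3 (vertical) in unexposed FLO1 and OE33 cells; each point is a gene, blue called with both shRNAs, orange called between the shRNAs, and the line marks equal effects. FLO1 has 12 genes called with both shRNAs and 2054 between them, OE33 2004 and 0.

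Some lists stayed without a call in every comparison tested. Bile acid and xenobiotic receptors and transporters were not called after ABS in FLO1 (0 of 5 genes; camera with Benjamini-Hochberg, adjusted p = 0.595) or OE33 (CYP24A1, at 0.445, the 1 of 8; adjusted p = 0.379), although CYP24A1 rose by 0.92 and 0.90 and ABCC3 fell by -0.72 and -0.74 with knockdown in OE33. Within lines, fibroblast and endothelial markers were tested in FLO1 alone, where ABS gave adjusted p = 0.23 and 0.0604 in camera with Benjamini-Hochberg. Between lines their adjusted p was 0.916 and 0.386 for ABS and 0.609 and 0.916 for knockdown (camera with Benjamini-Hochberg). Metallothioneins (adjusted p = 0.451 after ABS in FLO1 and 0.791 in OE33) and immune markers (0.476 and 0.805) were called once each, in the FLO1 interaction at the preset correlation (camera adjusted p = 0.0286 and 0.0077, and adjusted p = 0.335 and 0.067 with an estimated correlation).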

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

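The results in this part are tests of a difference between the 2 lines, OE33 minus FLO1, that passed their threshold; the list tests of these differences were chosen only after the gene results were seen. Culture medium differed with the line, so the lines and their media are compared together.

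For ABS in shControl cells 315 genes differed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among the 8 genes named for a lower response in OE33 were heat shock and immediate early genes. The 8 were HSPA6 (-5.53), HSPA1A (-3.285), HSPA1B (-3.20), NR4A1 (-2.49), DNAJB1 (-2.25), NR4A2 (-2.13), EGR1 (-2.045) and the DNAJB1-related cochaperone gene DNAJB5 (-1.90). On the other side stood COL6A1 (6.87), GFPT2 (4.90), CEACAM6 (3.18), FSTL1 (2.215), MT-TF (2.03), GOLPH3L (1.82), SDCBP2 (1.68) and OAS1 (1.67). The first 4 rest on very low counts in 1 line: COL6A1 went from 0 to 0.495 ± 0.715 CPM in OE33, GFPT2 from 0 to 0.206 ± 0.117 CPM, FSTL1 from 0.165 to 0.639 CPM, and CEACAM6 from 0.534 ± 0.632 to 0.0771 CPM in FLO1. In edgeR with Benjamini-Hochberg the adjusted p of COL6A1 rose to 0.412 without OE33 shControl ABS replicate 3, that of GFPT2 to 0.143 without OE33 shControl ABS replicate 2, that of CEACAM6 to 0.542 without FLO1 shControl replicate 1 and that of FSTL1 to 0.139 without OE33 shControl ABS replicate 3, and these 4 genes missed the threshold without other single libraries too. SDCBP2 missed it without FLO1 shControl replicate 1 (adjusted p = 0.379) and without FLO1 shControl ABS replicate 1, and OAS1 without FLO1 shControl replicate 1 (adjusted p = 0.271) and without FLO1 shControl ABS replicate 3. Each of these 6 genes missed it in a fit to only the groups compared, with an adjusted p of 0.0695 to 0.323.

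By list, heat shock (median difference -0.268, 5 genes lower), immediate early and AP-1 genes (-0.358, 7 lower) and cholesterol biosynthesis (-0.404, 10 lower) responded lower in OE33. Camera with Benjamini-Hochberg gave adjusted p = 2.01e-56, 2.07e-20 and 8.07e-23, and adjusted p = 5.28e-08, 0.00133 and 5.73e-08 with an estimated correlation. ER chaperone genes (-0.077, 5 lower), DNA replication genes (-0.137, 1 lower) and p53 targets (0.011, 6 lower, so that median and test differ in sign) were lower too (camera adjusted p = 3.76e-05, 5.27e-05 and 0.0121, and adjusted p = 0.0133, 0.00662 and 0.0185 with an estimated correlation). NRF2 targets (0.177, 3 higher) and interferon-stimulated genes (0.304, 2 higher) responded higher in OE33 (camera adjusted p = 6.74e-08 and 0.000802, and adjusted p = 0.00094 and 0.0133 with an estimated correlation).

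For the unexposed knockdown effect 1159 genes differed in edgeR with Benjamini-Hochberg. Lower in OE33 were UNC5B (-2.92), BHLHE41 (-2.59), PLXNA2 (-2.34), CALB2 (-2.24), FXYD3 (-2.236), SGCE (-2.10), IFI6 (-1.996) and the tight junction gene TJP3 (-1.82). FXYD3 missed the threshold without FLO1 shAPE1#1 replicate 3 (adjusted p = 0.218), and PASD1 without OE33 shAPE1#1 replicate 2 (adjusted p = 0.185) or any OE33 shControl library (adjusted p of at least 0.0672). Fitted values were higher in OE33 for CCL2 (6.44), KIRREL1 (6.28), CD70 (6.21), UCHL1 (6.01), NTN1 (5.91), ANTXR1 (5.81), MAGEA3 (5.15) and PASD1 (4.445). Each of these 8 genes read 0 CPM in OE33 shControl, so their fitted folds have no bound, and in unexposed OE33 knockdown libraries they read 0.0767 to 0.197% of their FLO1 level, the level at which reads carried over from FLO1 libraries are weighed as a pattern of their own. Their highest level in unexposed OE33 knockdown groups was 0.504 CPM (KIRREL1), against 470.6 CPM for CCL2 and 263.2 CPM for KIRREL1 in FLO1 shControl. By list, interferon-stimulated genes (-0.7, 11 lower) and p53 targets (-0.137) were lower in OE33 (camera with Benjamini-Hochberg, adjusted p = 7.18e-15 and 0.0121, and adjusted p = 2.09e-06 and 0.0185 with an estimated correlation). Immediate early and AP-1 genes (0.306, 7 higher) and the integrated stress response (0.262, 8 higher) were higher (camera adjusted p = 1.68e-11 and 6.01e-08, and adjusted p = 0.0133 and 0.00386 with an estimated correlation). The FLO1 side is a mean of both shRNAs, which differed from each other there in the interferon and integrated stress response lists.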

How the results depend on the processing

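The GC correction, the removal of genes at most 0.5% of their level in the other line, and leaving out libraries outside the groups compared were chosen after seeing the data. The cause of each move was not tested. With DESeq2 the counts were 33 (knockdown, FLO1), 807 (ABS in shControl, FLO1), 308 and 473 (ABS in shAPE1, FLO1 and OE33), 48 (knockdown after ABS, FLO1), 1 and 4 (interaction, FLO1 and OE33), 34 (between shRNAs, OE33) and 592 (ABS by line). Without a filter they were 28 (knockdown, FLO1), 41 (after ABS, FLO1), 3 and 3 (interaction) and 115 (between shRNAs, OE33). In a fit to only the groups compared they were 101 (knockdown, FLO1), 102 and 2157 (ABS in shControl, FLO1 and OE33), 553 and 143 (ABS in shAPE1), 7 (knockdown after ABS, FLO1), 5428 and 27 (between shRNAs), 99 (ABS by line) and 1847 (knockdown by line). With the GC correction they were 91 (knockdown, FLO1), 1491 and 2365 (ABS in shControl), 678 and 556 (ABS in shAPE1), 116 (knockdown after ABS, FLO1), 1 and 2 (interaction), 3741 and 12 (between shRNAs), and 951 and 2367 (by line); of the 506 genes called for ABS in FLO1, 504 were kept. RLE size factors moved no count by over 1.5 times. With an estimated correlation 19 of 56 list calls in FLO1 and 24 of 64 in OE33 were left. The GC correction kept 52 of the 56 and 58 of the 64. Without FLO1 shControl ABS replicate 2, 49 of the 56 were kept among 60 list calls.

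Leaving out single libraries gave 4 to 57 (FLO1) and 1462 to 2197 (OE33) for knockdown, 287 to 923 and 683 to 1582 for ABS in shControl, 123 to 456 and 116 to 339 for ABS in shAPE1, 10 to 142 and 1358 to 2114 for knockdown after ABS, 0 to 1 and 0 to 0 for the interaction, 1321 to 3437 and 0 to 27 between shRNAs, 202 to 887 for ABS by line and 866 to 1629 for knockdown by line. For APEX1 the ranges with shAPE1#1 and shAPE1#3 were -2.986 to -2.959 and -2.447 to -2.406 in FLO1, -3.105 to -2.98 and -3.148 to -3.114 in OE33, and after ABS -2.829 to -2.742 and -2.505 to -2.389 in FLO1 and -2.855 to -2.762 and -3.061 to -2.909 in OE33. Over 934 named gene comparisons and 13329 alternative values, 92.6% kept their call, 982 lost it and 0 changed sign. These genes were chosen because they were called, and mostly for a large change, in nearly the same libraries. A change of sign was therefore unlikely from the start, and no call could be gained.

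Replicate numbers did not pair the samples: libraries with the same number had a mean correlation of -0.02 in FLO1 (-0.288 to 0.095 over 45 pairs) and -0.014 in OE33 (-0.198 to 0.087), and 3 and 6 of 18 libraries correlated best with their own number. A replicate block gave 6 genes for knockdown in FLO1 and moved no other count by over 1.5 times.

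At an adjusted p of 0.01 the shared calls were 97 and 104 (ABS in shControl and in shAPE1, FLO1 and OE33), 2 and 778 (knockdown unexposed and after ABS), 4 and 1142 (both shRNAs unexposed), 7 and 1100 (both shRNAs after ABS) and 104 and 109 (ABS response with both shRNAs). Between lines they were 42 (ABS in shControl), 13 (ABS in shAPE1), 99 (shAPE1#1), 3 (shAPE1#3) and 2 (both shRNAs).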

Other observations

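Genes chosen in one line for their response to ABS were read in the other line, a comparison chosen only after the results were seen. The 858 genes that rose in OE33 shControl cells had a median of 0.103 in FLO1 shControl cells, with 597 in the same direction, and the 364 that fell had a median of -0.115, with 267 in the same direction. The medians of these genes were -0.009 and 0.052 in FLO1 shAPE1#1 cells (417 and 146 in the same direction) and 0.067 and -0.059 in shAPE1#3 cells (541 and 237). The 360 genes that rose in FLO1 shControl cells had medians of 0.168, 0.135 and 0.144 in OE33 cells with shControl, shAPE1#1 and shAPE1#3. SERBP1, which read lower with shAPE1#1 alone in FLO1, stood at 681.4 ± 31.5, 336.3 ± 27.9 and 346.6 ± 12.8 CPM in OE33 cells with shControl, shAPE1#1 and shAPE1#3. MTHFD1, which read 286.4 ± 1.02, 271.0 ± 6.46 and 132.1 ± 3.01 CPM in FLO1, stood at 222.4 ± 4.09, 206.0 ± 8.48 and 218.7 ± 2.71 CPM in OE33. Both genes are named here after their values were seen.

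Mitochondrial tRNA genes, MT-TF and MT-TV among them, were lower after ABS in 5 of 10 tested in FLO1 shControl cells (median -0.534), in 3 with shAPE1#1 (-0.402) and in 5 with shAPE1#3 (-0.436). In OE33 shControl cells 0 of 9 passed in edgeR with Benjamini-Hochberg (median -0.098), 2 were lower with shAPE1#1 (-0.274) and 1 with shAPE1#3 (-0.135). Unexposed knockdown in OE33 gave 6 and 7 higher of 9 (medians of 0.349 and 0.44); in FLO1 it gave 2 lower and 1 higher of 10 with shAPE1#1 (median 0.238) and 0 with shAPE1#3 (median -0.108). Mitochondrial genes took 3.34 ± 0.13% of the counts in OE33 shControl, 3.37 ± 0.25% with shAPE1#1 and 3.99 ± 0.10% with shAPE1#3. LYZ, an immune marker, KRT20, REG4 and VIL1 differed between groups of FLO1 from levels of at most 1.65 CPM.

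The tests of the 3 patterns below were chosen only after the results were seen; the counts of other splits were planned. The first pattern is that edgeR called 0 genes between the 2 OE33 knockdown groups while 2054 differed in FLO1. Differences of the FLO1 size missed in OE33 are argued against, since for 88.6% of genes (1564 of 1766) the 95% interval in OE33 leaves out the FLO1 difference. The share may be too high, as genes were chosen by FLO1 difference. The interval also omits the FLO1 error (median SE of all genes 0.142, OE33 0.116). A response proportional to APEX1 loss (ratio 0.815) is argued against for genes called with shAPE1#1 in exposed FLO1. Their unexposed slope, shAPE1#3 on shAPE1#1, was 0.022 (95% interval over genes -0.054 to 0.11). Steeper ones were untested. That both OE33 groups may carry 1 hairpin could not be decided: genes lowered by shAPE1#3 alone in exposed FLO1 had a median of 0.059 in OE33 shAPE1#3 cells, and those lowered by shAPE1#1 alone one of -0.077, 35.8% of their FLO1 change and under the 50% asked for. After that first definition of the gene sets failed 4 others were tried, and these 4 of 5 stayed above 50% in OE33 shAPE1#3 cells (53.8 to 75.4%). Only 1 of 5 gave all that 1 hairpin predicts, since in the OE33 group labelled shAPE1#1 the share was 18.1 to 52.5%. That group should carry the hairpin under either view, so a share under 50% does not count against 1 hairpin. In every definition the share was larger in OE33 shAPE1#3 cells, from 35.8 against 18.1% in the first to 75.4 against 52.5% with a 2-fold limit. The genes of shAPE1#3 have no positive control in OE33.

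The second pattern is that 56 genes specific to FLO1 read 0% of their FLO1 level in unexposed OE33 shControl libraries, 0 to 0.053% in exposed ones and 0.0408 to 0.197% in OE33 knockdown libraries, unexposed or exposed, so that the ranges of exposed shControl and knockdown libraries overlap. Their mean level in unexposed OE33 knockdown libraries followed that in FLO1 with a Spearman correlation of 0.583, so reads carried over from FLO1 libraries are a candidate explanation. Induction of single genes by the knockdown cannot be told apart from it, with an interquartile ratio of 2.22 in the share of the FLO1 level, since counts this low spread widely. In FLO1 libraries 81 genes specific to OE33 read 0.0937 to 0.216%. Without genes at that level knockdown in OE33 called 1993 genes in place of 2004, and VIM, at 0.159% of its FLO1 level, was among those left out.

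The third pattern is that FLO1 shControl ABS replicate 2 stood apart from its group. Its departure from the group mean followed transcript GC content with a Spearman correlation of 0.886, so a GC content bias between libraries may account for it. An exchange with an unexposed library is argued against: on genes that respond to ABS in both shAPE1 groups it stood at 1.036, where the other exposed libraries stood at 1.013 and 0.987 and unexposed ones at -0.049 to 0.047. Libraries of both lines showed such departures, with 7 and 8 of 18 over 0.5 in either direction. Departures from a group mean balance each other, so a shifted library gives the others of its group opposite departures. The GC correction lowered the coefficient of variation from 0.105 to 0.07 in FLO1 and from 0.082 to 0.063 in OE33. Because it is fitted to the departures of these libraries, some lowering was built in. The correction was chosen on these data, and whether GC content follows a step of the work was not tested.

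Other splits of the same libraries were counted for each result. A chance division of the libraries is argued against for ABS in shAPE1 cells (192 genes in FLO1, highest other split 0, and 253 in OE33, highest other 50), for knockdown in OE33 (2004, highest other 1991), knockdown after ABS in OE33 (1922, highest other 1915) and knockdown by line (1159, highest other 426), where 1 split of 100 each, the real one, gave as many. That is the lowest share these splits can give, and the shares were not adjusted over the results. Splits of libraries cannot exclude a difference between groups that comes from neither the shRNA nor ABS. The highest other splits of knockdown in OE33, unexposed and after ABS, keep the shControl libraries together and mix those of the 2 shRNAs. Chance cannot be excluded for knockdown in FLO1 (12 genes, highest other 888, and 5 of 100 splits gave as many), knockdown after ABS in FLO1 (24, highest other 2208, and 8 of 100) or ABS by line (315, highest other 2171, and 7 of 100). The highest other splits of knockdown in FLO1, unexposed and after ABS, keep the 3 shAPE1#1 libraries together and mix shControl with shAPE1#3, so they are not a measure of chance alone. That of ABS by line keeps the exposed and unexposed OE33 libraries as whole groups and mixes only FLO1, so it too is not a measure of chance alone. For the interaction the splits cannot decide, because a real count of 0 is reached by any split, 100 of 100 in both lines (highest other 239 in FLO1 and 0 in OE33). With 10 splits of 3 against 3 the splits are too few: ABS in shControl gave 506 genes in FLO1 (highest other 2538, with 2 splits as large) and 1306 in OE33 (highest other 0, with 1), and the shRNAs differed by 2054 genes in FLO1 (highest other 0, with 1) and 0 in OE33 (highest other 0, with 10, which a real count of 0 fixes). The FLO1 splits with several times the real count point to a structure of the samples, which for knockdown includes the grouping of the shAPE1#1 libraries. For ABS in shControl the split of 2538 genes sets shControl replicates 1 and 3 with shControl ABS replicate 2 against the rest, and the departures of its libraries from their group means correlated with GC content at 0.203, 0.729 and 0.886 on the one side and at -0.778, -0.878 and -0.688 on the other.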
